A study of Gossypium hirsutum with 3 samples.

How the data were processed

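Nuclei were prepared from protoplasts that a short enzyme digestion released from the surface layers of ovules of upland cotton (Gossypium hirsutum, genotype TM-1), per the labels' protocols. Their open chromatin was profiled with the 10x Chromium single-nucleus ATAC kit, with 1 library at each of 0, 1 and 2 days post-anthesis (DPA). The deposited matrices hold whole-number counts per called peak and barcode, with no normalization. Cell Ranger ATAC 2.1.0 wrote them, per the file headers, and the submitters' processing notes also name Signac. The 3 deposited peak lists differ, so each library was taken as having its own peaks. Of the matrix entries, 91.9%, 94.1% and 96.0% were even at 0, 1 and 2 DPA. Because 1 fragment can add 2 counts, every interval on a count ratio was computed with the counts divided by 2. The genome build behind the peaks is not given in the sources used here.

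Gene positions, gene types and names came from a table of NCBI genes of another named assembly. Its positions were checked against the peaks in windows of 5 Mb: in all 320 windows of each library, peaks met gene ends best within 200 bp of no shift. Because the builds were not named as the same, no coordinates of that table are printed, and the coordinates given are those of the peaks, counted from 1. The table held 67182 protein-coding genes on the 26 chromosomes, of which 740 carried a symbol beyond a locus number. Names are given with the chromosome in brackets. It holds no strand, exons or product descriptions. For that reason the planned promoter window was replaced by windows at both gene ends, from 1000 bp outside to 500 bp inside, and exon and intron classes were not analysed here. The planned lists by product description and the cell type markers by product description were not run, so clusters stay numbered. Sequence motifs and pairs of A and D gene copies from transcripts were not analysed here. Gene copies that share a name on matching A and D chromosomes were compared instead. In place of the planned lists, 33 lists of gene symbols were written after the reference names had been seen and before any count per gene was computed.

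Counts per gene were the sum over all peaks of a library that overlapped its end windows by at least 1 bp. A gene was measured in a comparison when both libraries held at least 50 such counts. A gene without a peak in a library has no value there, not 0. Ratios were taken on counts scaled to the total in peaks of the 26 chromosomes and then set against the median gene of the comparison. A gene was called higher or lower when its log2 ratio was at least 1 or at most -1 and the 95% interval of the ratio left out no change. "Rose" and "fell" are used of such genes alone. With 1 library per day there is no replicate check of any difference between days, and no p-value was computed. Each interval and each size-rule call covers counting error only. Shares carry exact Clopper-Pearson 95% intervals. The median of each list with at least 3 measured members was placed among 10000 random lists of the same size, matched in 10 bins on the mean level of the 2 libraries compared. The percentile describes these libraries. The matching was revised after list values had been seen, and matching on all 3 libraries is given as an alternative. Named genes were the 10 highest and 10 lowest named genes of each comparison with at least 100 counts in both libraries. For 2 against 0 DPA they also had the same sign in both steps. For each list described, the members with the highest and lowest ratio at 2 against 0 DPA and with the highest mean level were added. Results on some genes that this rule picks are left out of the text and the figures. Up to 2 genes at each end that carry a locus number alone were named too. Other called list members are named where a count is 5 or lower, and were chosen after their values were seen.

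The comparisons, the size rule, the rule for named genes and most other settings tried were fixed before the data were examined. The median gene as reference was chosen afterwards. So were 4 definitions. "Recurrent regions" are the 967 peaks of the 2 DPA library with counts in at least 10% of its barcodes, together with the peaks of the other libraries that overlap them. "Nucleus-rich barcodes" are those with under 50% of their counts in recurrent regions, and their ratios leave these regions out. "Shared peaks" are peaks that overlap a peak of the other library compared, introduced because a sum over separately called peaks moves with the length called. The overlapping peak can lie outside the windows of the gene, so shared peaks need not compare the same place. "Paired peaks", added last, are peaks at the ends of a gene that overlap a peak of the other library at the ends of the same gene. An overlap of 1 bp is enough and each peak keeps all its counts, so these sums can still move with called length. Paired peaks drop sites called in 1 library alone, which a real opening or closing would also leave, and counts per kb of called peak were computed as well.

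Peak sets were compared by an overlap of at least 1 bp, beside the same peaks shuffled 100 times within chromosomes. Location was assigned in the order gene end, gene interior, within 5 kb of a gene and more distant. Barcodes with at least 1000 counts were clustered within each library by TF-IDF, truncated singular value decomposition with 30 components, a graph of 20 neighbours and Leiden clustering at resolution 0.5. The component most correlated with depth was left out. The same clustering was run on nucleus-rich barcodes outside recurrent regions, an alternative added later, and gene ratios set each cluster against the others of its library. Doublets were not called or removed. No cluster sizes were compared between libraries.

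The size rule was tested on simulated data with known changes. At 1 against 0 DPA it called 50 of 50 genes raised by 1.3 on the log2 scale and 45 of 46 lowered by it, with 4 calls among 52840 unchanged genes. At 2 against 0 DPA the numbers were 49 of 50 and 28 of 35, with 2 calls among 29827. Each change was planted in 50 genes, and a denominator under 50 counts those still at the count minimum in both libraries. Of genes lowered by 2, only 33, 10 and 12 were tested at 1 against 0, 2 against 1 and 2 against 0 DPA. All of these were called. A gene that drops under the minimum is not called lower, which bears on the shares of calls that were higher. Splitting the barcodes of 1 library at random and comparing the parts gave 3, 14 and 3 calls at 0, 1 and 2 DPA. The simulation drew the counting error that the intervals assume, so few calls among unchanged genes were built in. Simulation and split both used the peaks of 1 library for the 2 sides. They hold no separately called peaks and give no rate of false calls between libraries. Clustering of simulated barcodes without structure gave 1 cluster in each library. A planted population with 2000 peaks changed 3-fold was recovered for 85.7%, 92.3% and 88.6% of barcodes at 0, 1 and 2 DPA. It had been missed at a resolution of 0.3, after which stronger planted changes were added. With 10000 peaks changed 2-fold, 99.4%, 99.7% and 92.4% were recovered, and with 3-fold changes 100% in each library.

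Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and Matplotlib 3.10.9. Settings fixed in advance varied the overlap rule, the peak lists, the gene window, the scaling, the count minimum, a pseudocount of 1 CPM, the barcodes used, their weight, the depth, the sequences counted and the clustering resolution. Peaks on unplaced scaffolds were left out of the comparisons because they carry no A or D assignment. Their counts are given among the results for a closer look.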

Results

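Open chromatin was profiled in nuclei from the surface layers of TM-1 cotton ovules, which include the epidermal cells that grow out into fibers, on the day of flowering and on the next 2 days. The comparisons address how accessibility at genes differed between 0, 1 and 2 days post-anthesis (DPA) while fiber growth begins. Each day was represented by 1 library, without replicates, so every difference is a difference between libraries, and the intervals cover counting error only. The 0, 1 and 2 DPA libraries held 2080, 5708 and 20066 barcodes and 112746310, 52073043 and 39428227 counts in peaks. The median barcode held 62512, 4320 and 1450 counts.

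A small set of regions took up much of this depth. The 967 recurrent regions, 912 kb in all, lay mostly on the A subgenome, with 690 on A, 260 on D and 17 on unplaced scaffolds. They held 12.6%, 44.3% and 78.1% of all counts at 0, 1 and 2 DPA. A block on A03 (96473127 to 96562822) alone held 1.24%, 4.60% and 7.93%, and a block on D06 (8671418 to 8703938) held 0.653%, 2.81% and 3.62%. The barcodes fell into nucleus-rich ones and others with most counts in these regions. Nucleus-rich barcodes numbered 1524 (73.3% of barcodes, 95% interval 71.3 to 75.2), 1170 (20.5%, 19.5 to 21.6) and 1073 (5.35%, 5.04 to 5.67). They held a median of 63868.5, 22154 and 4709 counts outside the recurrent regions, against 598, 530.5 and 155 in the other barcodes. Between 40% and 60% in recurrent regions lay 38, 103 and 171 barcodes.

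**Figure D1:**
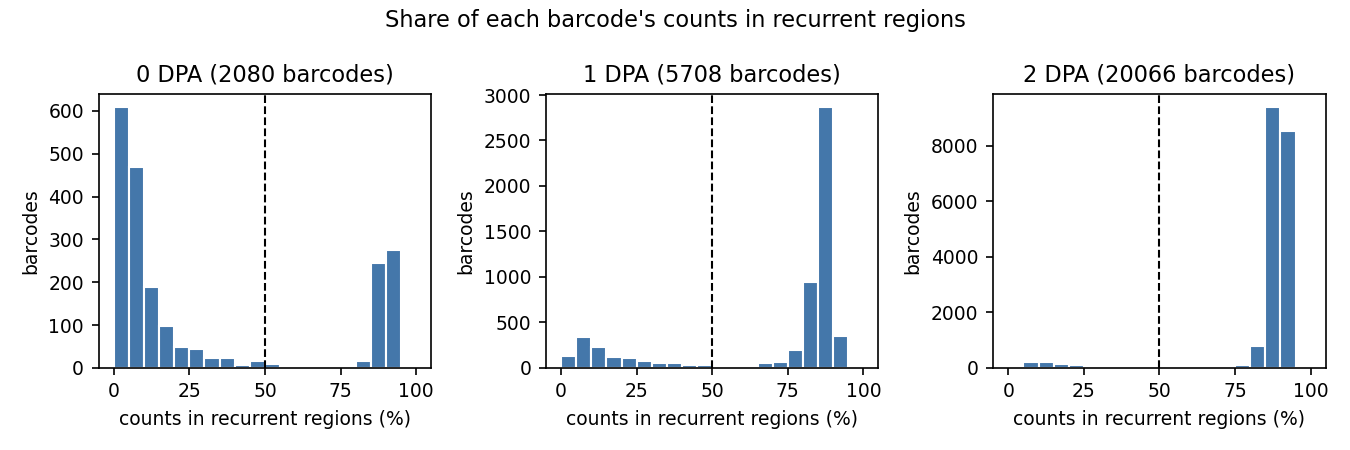
Number of barcodes (y axis) by the percent of their counts in the 967 recurrent regions (x axis) in each library, with the 50% limit of nucleus-rich barcodes dashed. The right-hand group grew from 556 of 2080 barcodes at 0 DPA to 18993 of 20066 at 2 DPA.

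From 0 to 1 DPA, the counts summed at gene ends rose at 1 of 4 measured expansin genes and at a MYB factor of fiber development. EXP1/EXPA1/EXPA15 (A10), an expansin of the kind that loosens cell walls, stood 1.07 higher on the log2 scale relative to the median gene (95% interval 0.44 to 1.66; 128 counts at 0 DPA and 77 at 1 DPA). The MYB factor myb109 (A05) rose by 1.42 (1.04 to 1.79; 281 and 215 counts). PAL (D01), which encodes phenylalanine ammonia-lyase, the entry enzyme of the phenylpropanoid pathway, rose by 1.14 (0.92 to 1.36; 914 and 576 counts), and PAS2-1 (A11), a dehydratase of very-long-chain fatty acid elongation, by 1.02 (0.74 to 1.29; 611 and 353 counts), but their largest peaks lay in different places on the 2 days. OPR3 (D05), an enzyme of jasmonate synthesis, was the one gene that fell among the 10 lowest of 616 eligible named genes, at -1.04 (-1.40 to -0.72; 1200 and 167 counts).

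In paired peaks, which overlap between the libraries at the gene but can differ in called length, EXP1/EXPA1/EXPA15 stood at 1.02 and passed the size rule. It was at 0.97 in nucleus-rich barcodes and at 0.93 with both restrictions, under the rule. For myb109, with 1041 and 1644 bp of called peak, the ratio was 1.16 in nucleus-rich barcodes and 0.72 in paired peaks. PAL had its largest peak at 63461965 to 63462876 at 0 DPA and at 63457105 to 63458087 at 1 DPA, and its ratio was 0.01 in paired peaks and -0.02 per kb of peak. PAS2-1 had its largest peak at 55412490 to 55413399 and at 55413899 to 55414907, and its ratio was -0.19 in paired peaks and -0.36 over the gene body with its flanks. OPR3, with 2718 and 838 bp, was at -0.41 in paired peaks and 0.55 per kb. In paired peaks of nucleus-rich barcodes 0 named genes were called at this step.

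Peaks in different places also lay behind the 2 highest named ratios. AT1 (A11) rose by 2.71 (2.41 to 3.02), with its largest peak at 8601701 to 8602567 at 0 DPA and at 8606186 to 8607910 at 1 DPA. MADS14 (D12), a MADS-box factor, rose by 2.51 (2.25 to 2.78), with peaks at 58298683 to 58299564 and at 58319779 to 58320385. In paired peaks their ratios were -0.35 and -0.07, with called lengths of 867 and 2635 bp for AT1 and of 882 and 1486 bp for MADS14. WRKY50 (D11) and pod1 (D12) rose by 1.47 and 1.51, and in paired peaks stood at 0.02 and -0.23. TPS1 (A01), BNL1924 (A05) and HSF12 (A08) rose by 1.95, 1.38 and 1.02, and in nucleus-rich barcodes stood at 0.10, 0.31 and 0.40. The largest peak of HSF12 lay at 126749265 to 126750258 at 0 DPA and at 126744959 to 126746084 at 1 DPA. The other 9 of the lowest named genes lay between -0.99 and -0.75 and were not called, among them HSF3 (A02) at -0.99 and DFR (A05), a reductase of flavonoid synthesis, at -0.97.

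Of the gene lists, brassinosteroid genes lay highest at this step. None of 8 measured members was called, yet their median of 0.34 exceeded 99.9% of matched random lists. DWF4 (A11) and DET2/GhDET2 (A04), enzymes of brassinosteroid synthesis, stood at 0.31 and 0.38, DET3 (A05) at 0.44 and SERK5 (D13) at -0.22. Membership rests on the symbol alone, and no role in brassinosteroid synthesis is implied for DET3 or SERK5. The list median was 0.11 in paired peaks, short of the outer 5%, and -0.06 per kb of peak. WRKY transcription factors lay low: of 83 measured, 1 rose (WRKY50) and 0 fell, and the median of -0.09 was at percentile 0.11. WRKY28 (A08) and WRKY15 (A02) stood at -0.93 and -0.90. In paired peaks the WRKY percentile was 6.12, and per kb the median was 0.01. MAP kinases had a median of -0.12 at percentile 1.95, with 0 of 23 called, and percentile 11.7 in paired peaks. In all, 3 of 32 lists fell in the outer 5%, where chance gives 1.6. The same 3 did so in nucleus-rich barcodes, with brassinosteroid genes, WRKY factors and MAP kinases at percentiles 99.87, 1.23 and 0.34. In paired peaks of nucleus-rich barcodes these were at 86.9, 2.16 and 12.9. In paired peaks over all barcodes none of the 3 lay in the outer 5%. There the fiber and epidermal cell fate factors, with 0 of 4 called, stood highest, at 0.44 and percentile 99.7, against 0.16 and percentile 88.0 over all peaks, where myb109 was higher. Expansins had a median of 0.02 at percentile 55.9, with EXP1/Exp2/EXPA1 (D10) at 0.06 (720 and 214 counts), and 0 of 4 were called in nucleus-rich barcodes. Their median was 0.272 (percentile 96.6) in paired peaks and 0.275 (percentile 99.0) in those of nucleus-rich barcodes, but -0.138 (percentile 9.73) in shared peaks. Of 16 phenylpropanoid genes 1 rose, PAL, with a list median of 0.09 at percentile 92.9. Among 10 measured genes of very-long-chain fatty acid synthesis 1 rose, PAS2-1, with a median of 0.07 at percentile 86.3. Of 15 peroxidases 2 rose, pod1 and pod3 (D03; 1.68). Of 23 MADS-box factors 1 rose, MADS14, and 1 fell, SEPALLATA1 (A07) at -1.33, and of 12 SPL factors 1 fell, SPL19 (D12) at -1.47. In paired peaks these were at -0.07, -0.49 and 0.14, and pod3 was not measured there.

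Of 53118 measured genes at this step, 1173 rose and 802 fell relative to the median gene, so that 59.4% of calls were higher. The median gene itself stood at -0.68 when counts were scaled to the total in peaks. Without setting ratios against it, 445 genes were higher and 7650 lower (5.50% higher), and 2.67% of calls were higher with scaling to the counts in peaks shared by all 3 libraries. In nucleus-rich barcodes 678 rose and 749 fell (47.5% higher). Genes that rose had a median of 1791 bp of called peak at 1 DPA and 969 bp at 0 DPA, and genes that fell 877 and 2242 bp. In paired peaks 505 of the 945 risen genes measured there were called again (53.4%), with a median of 1.05, but 11 of 795 fallen genes (1.38%), with a median of -0.10. In nucleus-rich barcodes 74 of 456 risen genes (16.2%) and 12 of 742 fallen genes (1.62%) were called again in paired peaks. Per kb of called peak the medians over all barcodes were 0.89 and -0.14.

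**Figure D2:**
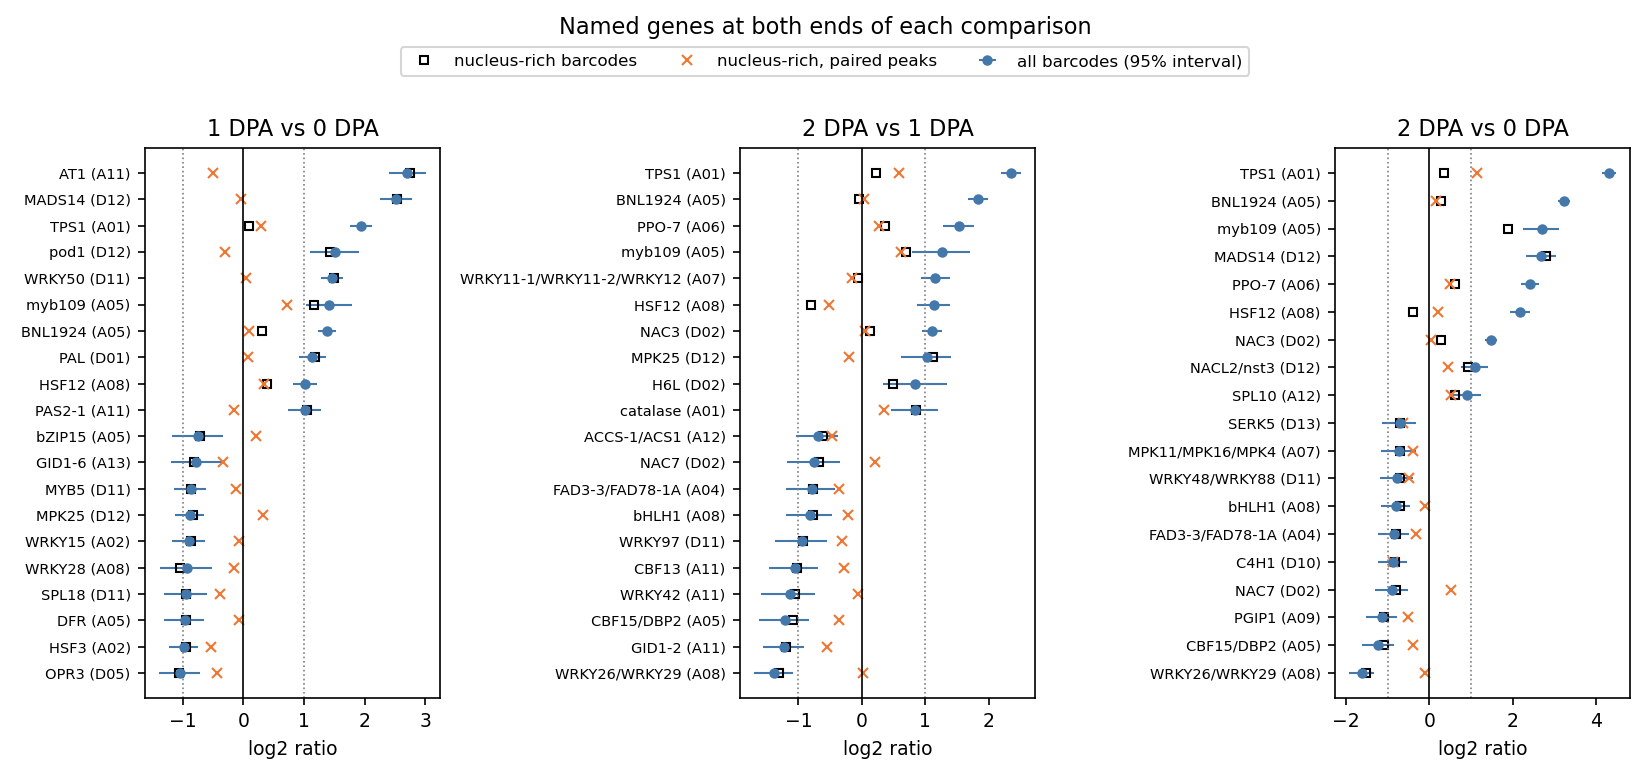
Log2 ratio (x axis) of the highest and lowest named genes of each comparison, over all barcodes with 95% counting intervals, in nucleus-rich barcodes and in paired peaks of these. Dotted lines mark the size rule of 1 and -1; AT1 at 1 against 0 DPA moves from 2.71 to -0.50, and WRKY26/WRKY29 at 2 against 0 DPA from -1.63 to -0.11.

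From 1 to 2 DPA, the counts summed at gene ends fell at a sucrose synthase gene, at gibberellin receptors and at a WRKY factor. Sus1 (A05), a sucrose synthase, fell by 1.35 on the log2 scale (95% interval -1.95 to -0.79; 546 counts at 1 DPA and 58 at 2 DPA), while susC (D06) rose by 1.28 (0.70 to 1.87; 131 and 86 counts). GID1-2 (A11) and GID1-1 (A12), which encode gibberellin receptors, fell by 1.23 (-1.56 to -0.91; 1559 and 180 counts) and 1.11 (-1.62 to -0.67; 697 and 87 counts). WRKY26/WRKY29 (A08) fell by 1.39 (-1.71 to -1.08; 1838 and 190 counts). The heat shock factor HSF23 (D11) fell by 1.63 (-2.23 to -1.08; 665 and 58 counts), and the lipid transfer protein gene FSLTP2/FSLTP3/GH3 (A10) rose by 1.05 (0.33 to 1.75; 100 and 56 counts). Sus1 (A05), susC, GID1-1, HSF23 and FSLTP2/FSLTP3/GH3 held under 100 counts at 2 DPA. They are named through their lists, not as the highest or lowest named genes of the step.

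In paired peaks Sus1 (A05) stood at -1.26 and kept its call, with -0.62 per kb. Neither Sus1 (A05) nor HSF23 was measured in nucleus-rich barcodes, and HSF23 was at -0.16 in paired peaks. WRKY26/WRKY29 kept its call in nucleus-rich barcodes but was at -0.07 in paired peaks, -0.40 per kb and 0.01 in the narrower end window. Its largest peak at 1 DPA, at 104773882 to 104775098 with 1149 of the 1838 counts, lay beside its one peak at 2 DPA, at 104775334 to 104776152. GID1-2 and GID1-1 were at -1.19 and -0.98 in nucleus-rich barcodes and at -0.59 and -0.52 in paired peaks. GID1-2 had 2993 and 921 bp of peak and a ratio of 0.18 per kb. The ratio of susC was 0.93 in nucleus-rich barcodes and 0.54 in paired peaks, with 879 and 1770 bp.

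Among the named genes that rose, TPS1 stood at 2.35 (2.19 to 2.52), BNL1924 at 1.83, the polyphenol oxidase PPO-7 (A06) at 1.53 (1.29 to 1.76), myb109 at 1.26 (0.80 to 1.71), WRKY11-1/WRKY11-2/WRKY12 (A07) at 1.16, HSF12 at 1.13, NAC3 (D02) at 1.10 and MPK25 (D12) at 1.02. In nucleus-rich barcodes these ratios were 0.23, -0.04, 0.37, 0.70, -0.07, -0.81, 0.14 and 1.13. MPK25, the one that passed the rule there, was at -0.23 in paired peaks, with 889 and 1966 bp called. The others kept their call in paired peaks over all barcodes, at 2.34, 1.81, 1.43, 1.16, 1.06, 1.25 and 1.00. In paired peaks of nucleus-rich barcodes 0 named genes were called higher. CBF15/DBP2 (A05) and CBF13 (A11), of the family of cold-response factors, fell by 1.21 and 1.06, and WRKY42 (A11) fell by 1.14. In paired peaks these were at -0.51, -0.32 and -0.13.

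By list, gibberellin genes stood lowest over all peaks. Of 5 measured members 2 fell, the receptors, and none rose, with GAI/GhGAI (A07), a repressor of the gibberellin response, at -0.78 and GAI4a (D06) at 0.18. The list median of -0.78 was at percentile 0.04 of random lists. It was -0.98 in nucleus-rich barcodes (percentile 0.10), -0.36 in paired peaks (1.51) and -0.38 with both restrictions (2.74). In nucleus-rich barcodes, with or without paired peaks, only 3 members were measured, and the 2 receptors were among them. In paired peaks over all barcodes sucrose-cleaving genes were at -0.34 (percentile 1.18, 4 measured) and actins at 0.54 (percentile 99.2, 5 measured). Over all peaks these 2 lists were at percentiles 9.59 and 71.6. Of 60 measured WRKY factors 1 rose and 6 fell, among them WRKY1/WRKY24 (A06) at -1.39 and WRKY50 at -1.26, which in paired peaks stood at -0.38 and 0.04. The WRKY median was -0.15, at percentile 0.89, and at percentiles 18.1 in nucleus-rich barcodes and 18.3 in paired peaks. Heat shock factors had a median of 0.14 at percentile 97.6, with 1 of 23 higher (HSF12) and 1 lower (HSF23), and the median was -0.08 per kb and -0.06 over the gene body. Polyphenol oxidases had a median of 0.70 at percentile 98.2, with 1 of 3 higher (PPO-7), PPO-3/PPO-6/PPO-8 (D06) at 0.70 and ppo (D06) at 0.01, and percentile 88.2 in nucleus-rich barcodes. In all, 4 of 26 lists fell in the outer 5%, where chance gives 1.3, and 1 of 22, the gibberellin genes, did so in nucleus-rich barcodes, and 0 did in paired peaks of these.

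Of 29769 measured genes at this step 1448 rose and 563 fell, 72.0% of calls higher, relative to a median gene at -1.48 on the total in peaks. Scaled to counts outside recurrent regions, 51.2% of calls were higher, 1023 in number. Without the median gene as reference 54 were higher and 25315 lower (0.213%). With scaling to the counts in peaks shared by all 3 libraries 0.0937% of calls were higher. In nucleus-rich barcodes 448 rose and 260 fell of 23248 (63.3%). Of the 784 risen genes measured there 397 were called again (50.6%), and of 282 fallen genes 206 (73.1%). Median called length was 1699 bp at 2 DPA and 1033 bp at 1 DPA for genes that rose, and 885 and 2469 bp for genes that fell. In paired peaks 775 of 1081 risen genes were called again (71.7%) with a median of 1.41, and 21 of 558 fallen genes (3.76%) with a median of -0.32. In nucleus-rich barcodes 86 of 221 risen genes (38.9%) and 13 of 257 fallen genes (5.06%) were called again in paired peaks. Per kb of called peak the medians over all barcodes were 0.92 and -0.19.

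**Figure D3:**
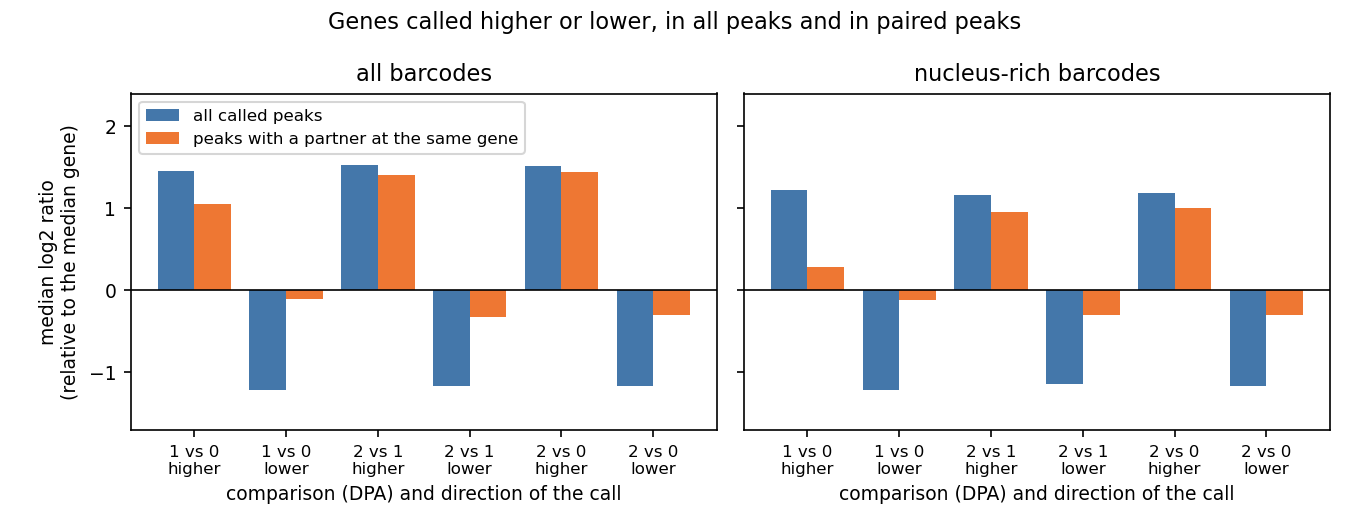
Median log2 ratio relative to the median gene (y axis) of the genes called higher or lower in each comparison and measured in paired peaks, over all called peaks and over paired peaks, in all barcodes and in nucleus-rich barcodes. At 1 against 0 DPA the median of genes called higher moved from 1.46 to 1.05 over all barcodes and from 1.23 to 0.29 in nucleus-rich barcodes.

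Across the whole interval, from 0 to 2 DPA, the counts summed at gene ends rose at the polyphenol oxidase PPO-3/PPO-6/PPO-8 and at myb109. PPO-3/PPO-6/PPO-8 rose by 1.33 (95% interval 0.80 to 1.79; 444 counts at 0 DPA and 85 at 2 DPA), with 1.29 in nucleus-rich barcodes, 1.66 in paired peaks and 1.64 with both restrictions. PPO-7 rose by 2.41 (2.20 to 2.62; 1279 and 519 counts) but stood at 0.60 in nucleus-rich barcodes. The factor myb109 rose by 2.70 (2.26 to 3.12; 281 and 139 counts), with 1.88 in nucleus-rich barcodes and 1.20 in paired peaks, and was not measured with both restrictions. Its largest peak lay at 99474087 to 99475127 at 0 DPA and at 99471117 to 99472069 at 2 DPA, with 85 of the 139 counts. WRKY26/WRKY29 fell by 1.63 (-1.94 to -1.33; 7700 and 190 counts), with -1.53 in nucleus-rich barcodes but -0.23 in paired peaks and -0.30 per kb, with 2760 and 819 bp of called peak. Its largest peak lay at 104774118 to 104775096 on A08 at 0 DPA, and its one peak at 2 DPA lay beside that, at 104775334 to 104776152. This comparison shares a library with each of the 2 steps, so its values are not independent of theirs.

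The other named genes that rose were TPS1 at 4.32 (4.15 to 4.49), BNL1924 at 3.23, MADS14 at 2.68, HSF12 at 2.17, NAC3 at 1.48 and NACL2/nst3 (D12) at 1.09. Nucleus-rich barcodes gave 0.34, 0.28, 2.81, -0.40, 0.27 and 0.91. With the restriction to paired peaks added, TPS1 stood at 1.13 and passed the rule. In paired peaks over all barcodes TPS1, BNL1924 and HSF12 kept their call, at 4.84, 3.10 and 2.70. There NAC3 and NACL2/nst3 were at -0.12 and 0.61, and MADS14 was not measured. Among genes with a locus number alone, the highest were LOC107926551 (A07) at 5.72 and LOC107927898 (D02) at 5.54. Of their 582 and 898 counts at 2 DPA 32 and 28 lay in nucleus-rich barcodes, where the ratios were not measured. The lowest were LOC107911771 (D11) at -1.65 and LOC107954965 (D07) at -1.61, at -0.53 and -0.28 in paired peaks. CBF15/DBP2 fell by 1.23 and PGIP1 (A09), an inhibitor of pectin-degrading enzymes of pathogens, by 1.14 (-1.51 to -0.79), and in paired peaks these were at -0.55 and -0.56. PGIP1 was at 0.40 per kb, with 3020 and 779 bp called. The remaining 7 of the lowest named genes lay between -0.91 and -0.70 and were not called. In paired peaks 12 named genes were called higher and 2 lower, Sus1 (A05) at -1.18 and MADS-9 (A12) at -1.09. In those of nucleus-rich barcodes 4 were called higher and 1 lower, MADS-9 at -1.27. At 2 against 1 DPA MADS-9 was also the 1 named gene called there, at -1.05.

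In the lists, gibberellin genes had a median of -0.91 at percentile 0.01, with 2 of 5 lower (GID1-2 at -1.07 and GID1-1 at -1.05) and GAI4a highest at 0.31. In paired peaks the median was -0.38 (percentile 1.67), and with both restrictions, over 3 measured members, the percentile was 16.3. Polyphenol oxidases, with 2 of 3 higher and ppo at 0.12, had a median of 1.33 at percentile 98.3 and of 1.66 in paired peaks. In nucleus-rich barcodes 1 of 3 was higher and the percentile was 96.2. Brassinosteroid genes, with 0 of 5 called, had a median of 0.46 at percentile 98.6 and of -0.20 per kb. Members ranged from DET3, listed by its symbol alone, at 0.94 and DWF4 at 0.46 down to SERK5 at -0.70. WRKY factors had a median of -0.16 at percentile 2.30 and 5.48 in nucleus-rich barcodes, with 1 of 60 higher and 2 lower. Heat shock factors were at 0.15 (percentile 98.1; -0.10 per kb), with HSF12 higher and HSF23 lower. The cell fate list of 7 fiber and epidermal genes had 3 measured members, of which myb109 rose, MML3/MML3_A12/MML3_D12 (D12) was at -0.33 and FDH/KCS45 (A13) at -0.31. FDH/KCS45 also belongs to the list of very-long-chain fatty acid synthesis. Of 4 measured sucrose-cleaving genes Sus1 (A05) fell by 1.55 (-1.18 in paired peaks, not measured in nucleus-rich barcodes) and susC rose (457 and 86 counts; 0.92 in nucleus-rich barcodes, 0.53 in paired peaks). The sucrose-cleaving list had a median of -0.33 (percentile 5.52), and of -0.38 (percentile 0.78) in paired peaks. FSLTP2/FSLTP3/GH3 rose by 1.17 and was at 1.04 in paired peaks, and the annexin gene annexin/Anx1/ax (D11) of the same list was at -0.58. In all, 5 of 26 lists fell in the outer 5%, where chance gives 1.3, and 1 of 22, the gibberellin genes with 3 measured members, in nucleus-rich barcodes.

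Of 29873 measured genes 1606 rose and 515 fell (75.7% higher), relative to a median gene at -2.18. Counts outside recurrent regions gave 1028 higher and 1158 lower (47.0%), the absence of a median reference 393 and 28694 (1.35%), and peaks shared by all 3 libraries 1.19% higher. In nucleus-rich barcodes 449 rose and 226 fell (66.5%), and 418 of the 851 risen genes measured there were called again (49.1%). Genes that rose had a median of 1700 bp of called peak at 2 DPA and 1656 bp at 0 DPA, and genes that fell 878 and 2491 bp. In paired peaks 928 of 1294 risen genes (71.7%) and 21 of 509 fallen genes (4.13%) were called again, with medians of 1.45 and -0.30. In nucleus-rich barcodes 139 of 272 risen genes (51.1%) and 7 of 223 fallen genes (3.14%) were called again in paired peaks. Per kb of called peak the medians over all barcodes were 1.09 and -0.21.

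Copies that share a name on matching A and D chromosomes differed most for WRKY29. The copy on A08, WRKY26/WRKY29, held 7700 counts at 0 DPA against 711 on D08, a log2 ratio of 3.44 (95% interval 3.28 to 3.60), and 3.35 at 1 DPA. With 2760 and 1671 bp of called peak at 0 DPA, the ratio per kb was 2.71, and 3.06 at 1 DPA. The expansin EXP1 lay towards the D copy at 0 DPA, with 128 counts on A10 and 720 on D10 (-2.49, -2.90 to -2.11), 968 and 2433 bp called and -1.16 per kb. At 1 DPA it was at -1.48 but at 0.35 per kb. For WRKY70, at -0.54, -0.68 and -1.21 on the 3 days, and MYB5, at 0.41, 1.02 and 0.91, the sign also turned per kb on the later days, to 0.55 and 0.47 for WRKY70 and to -0.01 and -0.34 for MYB5. FAD3-1, a fatty acid desaturase, was near balance at -0.04, -0.09 and -0.07, and its intervals included 0. The pairs rest on a shared symbol alone.

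Peaks of the later libraries lay mostly within those of the earlier ones. Of the 1 DPA peaks 92.7% overlapped a 0 DPA peak, where shuffled peaks gave 17.7%, and of the 2 DPA peaks 90.9% overlapped a 0 DPA peak (17.5%) and 89.1% a 1 DPA peak (14.2%). In the other direction 73.8% of 0 DPA peaks met a 1 DPA peak and 47.5% a 2 DPA peak, while the number of peaks fell with depth from 238736 to 189255 and 123924. Merged over libraries, 106279 of 256399 regions (41.5%) were found on all 3 days, 57449 (22.4%) at 0 DPA alone, 11091 (4.33%) at 1 DPA alone and 8698 (3.39%) at 2 DPA alone. For equal lists of the 20000 peaks with most counts per kb, 56.8% of merged regions were in the lists of all 3 days. In the list of 0, 1 or 2 DPA alone were 6.36%, 3.86% and 11.9%. A region in 1 of these lists alone can still hold a weaker peak on another day.

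By number of peaks, gene ends were the largest class on each day, with 45.2%, 48.3% and 47.0% of peaks at 0, 1 and 2 DPA and 12.8% to 13.1% of shuffled peaks. More distant peaks, over 5 kb from a gene, made up 27.8%, 25.5% and 28.2%, against 66.8% to 67.2% when shuffled. By counts, gene ends held 48.2%, 35.6% and 21.2% and distant peaks 28.2%, 43.4% and 59.8%. Outside recurrent regions, gene ends held 52.9%, 51.3% and 44.0% of counts and distant peaks 22.6%, 24.8% and 32.6%. Of the counts outside these regions, 0.834%, 10.9% and 40.4% came from barcodes that were not nucleus-rich. Shares outside recurrent regions are therefore not those of nucleus-rich barcodes alone, least of all at 2 DPA. The A subgenome, 63.4% of the span with peaks and 49.3% of genes, carried 52.0%, 52.0% and 53.7% of peaks. Per Mb it held 85.7, 67.9 and 46.0 peaks against 137, 109 and 68.4 on D. Counts at gene ends were split evenly, with 50.6%, 50.5% and 50.4% on A, whereas 55.6%, 61.4% and 67.9% of all counts lay on A, and 53.5%, 54.5% and 56.4% outside recurrent regions.

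Within the libraries, nucleus-rich barcodes formed 6 clusters at 0 DPA, 3 at 1 DPA and 2 at 2 DPA. With all barcodes of at least 1000 counts there were 6, 7 and 11 clusters, of which 5, 2 and 1 were mostly nucleus-rich. Genes of very-long-chain fatty acid synthesis, which makes the lipids of epidermal cuticle, set some clusters apart. At 0 DPA their median stood at 0.31 in clusters 1 and 2, at percentiles 99.90 and 99.98 of random lists, with 0 of 11 and 0 of 10 members called. Cluster 2 was also high for sucrose-cleaving genes (0.35, percentile 99.7) and MAP kinases (0.18, percentile 99.9), with 0 of 5 and 0 of 23 called. In cluster 4 of 0 DPA 3 of 9 members of the fatty acid list were lower, with a median of -0.17 (percentile 3.96). At 1 DPA cluster 2 had KCS38 (A01), a ketoacyl-CoA synthase, at 1.03, and cluster 3 had a list median of -0.38 (percentile 0.15) with 3 of 9 members lower: FDH/KCS45 at -1.28, KCS38 at -1.26 and KCS48 (D07) at -1.01. Cluster 3 was also low for phenylpropanoid genes (-0.35, percentile 0.03) and gibberellin genes (-0.42, percentile 0.13) and high for NAC factors (0.25, percentile 99.8), with 0 of 12, 0 of 9 and 0 of 15 members called. The fiber and epidermal cell fate list was high in cluster 2 of 0 DPA (0.30, percentile 98.7) and cluster 2 of 1 DPA (0.46, percentile 99.0). In both, 0 of 4 members were called, and cluster 1 of each day stood near them, at 0.31 (percentile 97.1) and 0.33 (percentile 94.3). The list was low in 0 DPA clusters 4 (-0.47, percentile 1.71) and 5 (-0.49, percentile 0.16). In each of these only 3 of its 7 members were measured, of which 1 was lower in cluster 4 and 0 were called in cluster 5. The cell fate list shares FDH/KCS45 with the fatty acid list, so the 2 lists are not separate evidence.

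Cluster 4 of 0 DPA was led by MADS20 (A04) at 2.09 and MADS-11 (D04) at 1.74, with MADS-box factors as a list at 0.22 (percentile 99.9; 2 of 23 higher). Its lowest genes included PAL at -1.38, KCS38 at -1.36 and TT12 (A12), a flavonoid transporter, at -1.34. Cluster 5 of 0 DPA was led by SPL22 (A13) at 1.92, PME2 (D11) at 1.84 and MADS28 (A13) at 1.63. Polyphenol oxidases were high in cluster 3 of 0 DPA (0.39, percentile 98.2; 0 of 5 called) and cluster 1 of 1 DPA (0.56, percentile 99.7; 1 of 4 called). Cluster 6 of 0 DPA had a median of 34.3% of counts in recurrent regions, against 5.37% to 7.12% in the others, and was led by TPS1 at 1.83. At 2 DPA, with 698 and 375 barcodes, 930 genes were measured and no named gene was called. The clusters were drawn from the same counts, so these ratios describe them and are no test. Over all clusters, 17 of 180 list medians at 0 DPA and 13 of 84 at 1 DPA lay in the outer 5%, where chance gives 9.0 and 4.2.

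**Figure D4:**
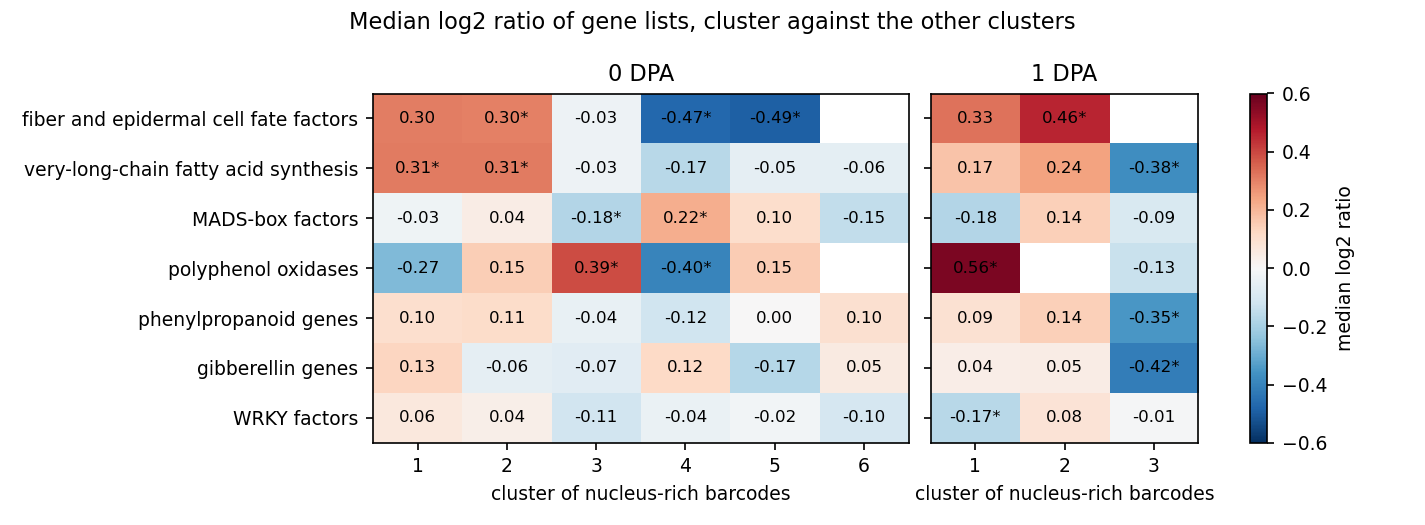
Median log2 ratio (color scale) of 7 gene lists (rows) in each cluster of nucleus-rich barcodes against the other clusters of its library (columns), at 0 and 1 DPA. Asterisks mark medians in the outer 5% of 10000 random lists and blank cells lists with fewer than 3 measured members; fatty acid synthesis ranges from -0.38 in cluster 3 of 1 DPA to 0.31.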

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

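Every test in this part was chosen after the patterns had been seen. Peaks on unplaced scaffolds, which no comparison uses, held 302606 counts at 0 DPA, 394202 at 1 DPA and 475056 at 2 DPA, a signal in data left out of the comparisons. These were 0.268%, 0.757% and 1.21% of all counts, and 62.1%, 82.4% and 91.4% of them lay in recurrent regions. The largest peak lay on scaffold 382 at 0 DPA and on scaffold 747 at 1 and 2 DPA.

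Recurrent regions took a growing share of counts, from 12.6% to 78.1%. Annotated ribosomal RNA genes are argued against by the 0% of the 2 DPA counts in these regions that lay within 5000 bp of one, although arrays missing from the gene table stay open. A chromatin change inside nuclei stays open: barcodes with under 1000 counts outside the regions held 94.8% of these counts but were 94.4% of barcodes, and inside nucleus-rich barcodes the median share rose from 6.29% to 11.7% and 17.0%. That share grew although the median recurrent counts of a nucleus-rich barcode became fewer, at 4263.5, 2991 and 870. Their outside counts dropped more steeply, from 63868.5 to 22154 and 4709. In the other barcodes the median recurrent counts were 4821, 3197.5 and 1261. DNA from outside nuclei in every droplet would give similar amounts whatever else a barcode holds, and of 3 equal groups by outside counts, among barcodes with as many of these as the smallest barcode's total, the lowest held 1.15, 1.27 and 0.694 times the recurrent counts of the highest (intervals 0.980 to 1.31, 1.15 to 1.49 and 0.576 to 0.828). That stays open too, since the 2 DPA interval reaches below 2/3 and the rank correlation of recurrent with outside counts over all barcodes was -0.05, 0.32 and 0.51.

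Relative to the median gene, 1606 genes were called higher at 2 than at 0 DPA, and the tests concern the size of their ratios, not their number against the 515 called lower, which turned to 1028 and 1158 when counts outside recurrent regions set the scale. Counts in nucleus-poor barcodes are not the whole cause: with no count minimum, and the 93 genes without a value taken at 0, the median log2 ratio of all 1606 in nucleus-rich barcodes was 0.92 against 1.54, or 59.6% (56.2 to 62.6). Nucleus-rich barcodes themselves held a median of 6.29% of counts in recurrent regions at 0 DPA and 17.0% at 2 DPA. Whether the source of counts in nucleus-poor barcodes also adds to nucleus-rich ones is therefore not decided. Their counts also helped to choose the 1606 genes. Peaks without a partner at the same gene are not the whole cause either, since in paired peaks, with 312 genes taken at 0, the median was 73.5% of that over all peaks (70.4 to 76.9). The 2 together stay open, since in paired peaks of nucleus-rich barcodes only 650 of the 1606 genes had a value, of which 160 were called. Over these 650 the median was 49.7% (45.3 to 54.4). With the other genes taken at 0 it is 0% by construction, which decides nothing. A difference between the days and a difference between the libraries stay open too, since each day is a single library.

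In nucleus-rich barcodes 678 genes rose and 749 fell from 0 to 1 DPA. Peaks without a partner at the same gene in the other library are consistent with both: in paired peaks the median of the risen genes kept 2.57% of its size (0 to 7.31), with 222 that had no value there taken at 0, and 23.4% (19.6 to 29.6) over the other 456, and that of the fallen genes kept 9.57% (7.93 to 12.2). A site that opened or closed in nuclei would leave such a peak as well, so this does not part a change in chromatin from peak calling at unequal depth. A different mix of the clustered populations stays open, because only 124 and 17 genes were called in paired peaks, although their median within 3 pairs of clusters (profile r 0.419 to 0.497) was at least 98.9% and 78.7% of that over all nucleus-rich barcodes. The width of called peaks, the library and the biology of the first day after anthesis stay open.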

How the results depend on the processing

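Chosen after the results were seen were the settings of nucleus-rich barcodes, shared peaks, paired peaks, either of these 2 in nucleus-rich barcodes, counts per kb, recurrent regions left out, scaling on counts outside them, and lists matched on all 3 libraries. No paired analysis was possible because each day had 1 library. Of 60 named gene comparisons, 17 kept their call under all of up to 16 alternatives, 43 did so in nucleus-rich barcodes, 43 of 59 in shared peaks, 39 of 59 in paired peaks, and 28 changed under a setting fixed in advance. In these counts, and in those over all settings, a gene called neither higher nor lower that stayed so also kept its call. Among all named genes, paired peaks gave 3 calls higher and 0 lower at 1 against 0 DPA. They gave 9 and 3 at 2 against 1 DPA and 12 and 2 at 2 against 0 DPA. Over all settings 721 values of named genes kept their call, 136 were weaker, 13 stronger and 40 reversed, and of list medians 73 were the same, 72 weaker and 6 reversed. Summary values stayed the same 77 times and moved 136 times. Thinning to the smallest library, median-of-ratios scaling, barcodes with at least 1000 counts and resolution 0.3 moved no count of calls, lists or all clusters by over 1.5 times and reversed nothing. At resolution 0.3 the clusters of all barcodes that were mostly nucleus-rich did move, to 3 and 1 at 0 and 1 DPA from 5 and 2. Pairs of A and D copies from transcripts and sequence motifs, with their alternatives, were not run. Some named genes and lists gave no value with at least 200 counts, in shared or paired peaks or in those of nucleus-rich barcodes. Depth limits the 2 DPA library most, where 29873 genes could be compared with 0 DPA against 53118 at 1 DPA. Where no construction is named, the cause was not tested.

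Values for 3 pairs of days follow the order 1 against 0, 2 against 1 and 2 against 0 DPA, and values for days the order 0, 1 and 2 DPA. Overlap of 1 DPA peaks with 0 DPA peaks, 2 DPA with 0 DPA and 2 DPA with 1 DPA was 91.3%, 88.9% and 87.2% at 50% of both peaks. It was 90.6%, 87.5% and 86.1% for midpoints within 250 bp, 87.2%, 77.1% and 80.4% for the top 20000 peaks, and 97.8%, 98.3% and 98.2% for peaks with at least 50 counts. For the top 20000 without recurrent regions it was 86.7%, 76.1% and 79.7%. Gene-end shares were 54.5%, 57.4% and 55.6% with the 2000 bp window, 37.6%, 40.6% and 39.8% with the 500 bp window, wider and narrower by construction. They were 50.1%, 47.9% and 45.3% for the top 20000 peaks, and 52.2%, 49.8% and 47.3% for these without recurrent regions. A shares were 57.9%, 58.1% and 58.5% of the top 20000 peaks, 55.6%, 61.4% and 67.9% of counts, 50.6%, 50.5% and 50.4% of gene-end counts, and 53.5%, 54.5% and 56.4% of counts outside recurrent regions.

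Genes higher and lower numbered 445 and 7650, 54 and 25315, and 393 and 28694 when scaled to the total in peaks without the median gene, which moves every gene by the same amount. Scaled to the counts in peaks shared by all 3 libraries they were 378 and 13756, 25 and 26665, and 349 and 29024, and with scaffolds in the total 440 and 7854, 52 and 25379, and 392 and 28714. Scaled to counts outside recurrent regions 975 were lower in the second pair, and 1028 higher and 1158 lower in the third. With at least 20 counts, which admits more genes, 1313 were lower in the first pair, then 2397 higher and 1962 lower, and 2825 and 1886. With no minimum these were 1403, 2480 and 2300, and 2945 and 2250. With at least 200 counts, which leaves fewer genes, they were 624 and 66, 506 and 3, and 521 and 2, and 0 lists lay in the outer 5% in each of the later pairs. A pseudocount gave 776 higher and 245 lower in the first pair and 221 and 216 lower in the others. Equal weight per barcode gave 1903 higher in the first pair, 1046 lower in the second, and 2578 higher and 970 lower in the third, with 3 lists there. The gene body with 2000 bp flanks gave 860 and 828 lower in the later pairs, with 1 and 2 lists. Lists matched on all 3 libraries gave 2 in the second pair.

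Nucleus-rich barcodes gave 678 higher in the first pair, 448 higher and 260 lower in the second and 449 and 226 in the third, with 1 list in each of the later pairs. They formed 3 clusters at 1 DPA and 2 at 2 DPA. Resolution 1.0 gave 10 clusters at 0 DPA and 17 at 2 DPA, and barcodes with at least 2000 counts gave 5 at 2 DPA. Shared peaks gave 178, 111 and 101 lower, with 1 list in the first pair and 3 in the third. Counts per kb gave 260, 259 and 337 lower, with 1 list in the third. Nucleus-rich barcodes with shared peaks gave 381 and 174, 241 and 60, and 397 and 49, with 0 lists in each of the later pairs. Paired peaks, which leave out sites called in 1 library alone, gave 586 and 15 in the first pair, 928 and 33 in the second and 34 lower in the third, with 1 list in the first and 3 in the third. In nucleus-rich barcodes they gave 124 and 17, 134 and 20, and 258 and 12, with 0 lists in each of the later pairs.

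Reversed in the 500 bp window were WRKY50 (-0.068), HSF12 (-0.39) and PAS2-1 (-0.40) at 1 against 0 DPA, NAC3 (-0.024) and WRKY26/WRKY29 (0.007) at 2 against 1 DPA and NAC3 (-0.013) at 2 against 0 DPA. With the gene body, PAL (-0.16) and PAS2-1 (-0.36) at 1 against 0 DPA and the median of heat shock factors (-0.064) at 2 against 1 DPA reversed. In nucleus-rich barcodes BNL1924 (-0.039), WRKY11-1/WRKY11-2/WRKY12 (-0.065) and HSF12 (-0.81) reversed at 2 against 1 DPA and HSF12 (-0.40) at 2 against 0 DPA. In shared peaks AT1 (-0.35) and MADS14 (-0.07) reversed at 1 against 0 DPA and MPK25 (-0.23) at 2 against 1 DPA. With shared peaks of nucleus-rich barcodes AT1 (-0.51) and MADS14 (-0.042) reversed at 1 against 0 DPA, and WRKY11-1/WRKY11-2/WRKY12 (-0.15), HSF12 (-0.52) and MPK25 (-0.20) at 2 against 1 DPA. In paired peaks AT1 (-0.345), MADS14 (-0.069), pod1 (-0.23) and PAS2-1 (-0.193) reversed at 1 against 0 DPA, MPK25 (-0.225) at 2 against 1 DPA and NAC3 (-0.118) at 2 against 0 DPA. In paired peaks of nucleus-rich barcodes AT1 (-0.504), MADS14 (-0.041), pod1 (-0.304) and PAS2-1 (-0.156) reversed at 1 against 0 DPA, and WRKY11-1/WRKY11-2/WRKY12 (-0.154), HSF12 (-0.514), MPK25 (-0.197) and WRKY26/WRKY29 (0.020) at 2 against 1 DPA. Per kb, PAL (-0.015), OPR3 (0.55) and the medians of brassinosteroid genes (-0.064) and WRKY factors (0.011) reversed at 1 against 0 DPA. So did MPK25 (-0.41), GID1-2 (0.18), CBF13 (0.12) and heat shock factors (-0.084) at 2 against 1 DPA, and PGIP1 (0.40), brassinosteroid genes (-0.20) and heat shock factors (-0.10) at 2 against 0 DPA.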

Other observations

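The values in this part were chosen after the results had been seen. Transfer RNA genes had a peak at their ends at 92.7%, 89.9% and 82.0% of 1440 genes at 0, 1 and 2 DPA, and transcribed pseudogenes at 90.2%, 90.2% and 80.4% of 92. Of 130 genes of the miscellaneous RNA type 96.2%, 91.5% and 76.9% had one. Protein-coding genes had 89.2%, 84.7% and 66.5%, and long noncoding RNA genes had 75.5%, 69.0% and 56.5%. Small nuclear RNA genes had 70.1%, 68.1% and 59.4%. Of 6497 pseudogenes 4548, 4130 and 3122 had one. Ribosomal RNA genes had 18.5%, 22.8% and 18.2%, and small nucleolar RNA genes 5.53%, 5.19% and 4.53%.

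Recurrent regions overlapped 15 of 1440 transfer RNA genes (1.04%, 95% interval 0.584 to 1.71) and 97 of 67182 protein-coding genes (0.144%, 0.117 to 0.176). They also overlapped 4 of 92 transcribed pseudogenes (4.35%, 1.20 to 10.8). Of 611 ribosomal RNA genes 0 overlapped them, with an upper limit of 0.602%. Barcode sequences found in more than 1 library numbered 9 for 0 and 1 DPA, 70 for 0 and 2 DPA and 172 for 1 and 2 DPA.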
